A study of Mus musculus with 24 samples.

How the data were processed

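The series holds polyA RNA sequencing of 24 mouse samples, skin and dorsal root ganglia (DRG) of control and LL37-injected (rosacea model) mice, with 6 libraries in each of 4 groups. RNA was extracted with an RNeasy Mini Kit and QIAzol, and the groups were taken from the sample titles. The submitters' processing notes name bcl2fastq 2.20.0, Trimmomatic (version not given in the sources used here), HISAT2 2.1.0 and StringTie 2.1.3b with the mouse genome GRCm38/mm10. How reads were counted per gene, with which strand setting and filters, is not given in the sources used here. The deposited table holds 45777 genes with 3 kinds of columns for each library. Read counts per gene were deposited by the authors without normalization, as whole numbers that sum to a different total in each library. FPKM values (scaled to library size and transcript length) were computed by the authors and were not used here. TPM values (scaled to transcript length, then to library size) were computed by the authors and served in alternative settings alone. Coordinates are of GRCm38.p6 genes from RefSeq, and strand and overlap with neighbouring genes could not be taken into account.

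Total counts per library ranged from 45238735 to 68396846, so 1 count corresponded to a small fraction of a CPM: a floor of 3 counts over a group was 0.0094 CPM in control skin and 0.00868 CPM in control DRG. Floors cover counting error only, and bootstrap intervals the spread between libraries. The intervals were computed on log2 CPM, while the medians and the ratio they stand beside come from edgeR's log2 fold changes. They therefore need not be centred on these values. None of the 60 pairs of libraries within a group was a duplicate: the lowest chi-square per gene was 10.7.

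The following choices were made before the data were examined. Each tissue was fitted alone in edgeR 4.0.16 (R 4.3.3) with filterByExpr on the groups, TMM scaling, robust quasi-likelihood (QL) dispersion and the QL F test, without covariates. Genes were called at a Benjamini-Hochberg (BH) adjusted p under 0.05 over all genes tested. The difference of the model effect between skin and DRG was tested as a contrast of the 4 group means in 1 fit of 24 libraries, over genes that passed the filter in both tissues. The overlap of called genes was tested with Fisher's exact test, two-sided, over the same genes. Levels are TMM-normalised CPM. A fold against a group with no counts was given as a bound against a floor of 3 counts over the group.

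There were 36 gene lists, of cell types, pathways and technical responses, of which 27 applied to skin and 29 to DRG. Lists with at least 5 measured members were tested with camera in limma 3.58.1 (preset correlation 0.01, two-sided) on log2 CPM with a prior count of 2, with BH adjustment over the lists of a tissue. Beside each list stand the members called over all genes and those called adjusted over the list alone, and the result of camera with an estimated correlation. Genes were named by a rule. Among called genes with a mean of at least 1 CPM in a group, predicted gene models left out, it took the 8 with the largest change and the 4 with the smallest p in each direction. From each list it took up to 4 members with the smallest p, and some genes linked to rosacea, sensory neurons or gabapentin were always given. Where no gene fell, the 4 decreases with the smallest p were given as not passing, and for the tissue difference the 4 genes with the smallest p in each direction. An older symbol was tried for 2 list members.

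The tests were checked on simulated negative binomial counts with the means and spread of these libraries. In simulated skin, edgeR recovered 32.8, 58.2 and 93.9% of genes changed 1.5-fold, 2-fold and 4-fold, and 8 of 131 calls were false. In simulated DRG it recovered 64.2, 86.6 and 98.5%, and 7 of 173 calls were false, and for the tissue difference it recovered 24.2, 66.4 and 96.7%. Among DESeq2's calls 29.2% were false in simulated skin and 16.5% in simulated DRG. In simulated skin edgeR and DESeq2 called 131 and 209 genes, against 3892 and 5551 in the real skin data. With so many more calls the limit on unadjusted p differs, so the skin recovery rates and false shares need not carry over. Camera in both forms and fry called the changed list and 0 unchanged lists in either tissue. Genes were simulated independently of each other, so this check says nothing on lists of correlated genes.

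Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no filter, a filter of at least 1 CPM in 6 libraries, dispersion without the robust option, all 24 libraries in 1 fit, a replicate block, 1 surrogate variable from sva 3.50.0, limma trend on log2(TPM + 1) and log2(TPM + 0.1), an absolute log2 fold change of at least 1, and each library left out in turn. For lists, camera with an estimated correlation, fry, RLE factors and the block were tried, and for the tissue difference scaling within each tissue. After the data were seen, a hair score covariate (mean log2 CPM of the hair follicle list) in skin, the omission of DRG control 5 with DRG model 5, and the omission of each library for the list tests were added. For each count of calls, 100 splits of the same libraries into groups of the same sizes were drawn with a fixed seed. In groups of 6, a value was set apart when Dixon's ratio exceeded its 95% critical value. No library was left out of the comparisons reported. Results of 1 gene are not reported here, though the counts of genes include it.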

Results

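RNA sequencing libraries were made from skin and from dorsal root ganglia (DRG, the clusters of sensory neuron cell bodies beside the spinal cord) of female BALB/c mice aged 6 weeks. The model mice had received LL37, a human cathelicidin antimicrobial peptide used to induce rosacea-like inflammation, by injection into the skin at 320 µM in 40 µL. There were 4 groups of 6 libraries: control skin, model skin, control DRG and model DRG, 24 libraries in all. Total counts per library were 45238735 to 64547448 in control skin, 46549562 to 63531350 in model skin, 52273676 to 63544026 in control DRG and 47801198 to 68396846 in model DRG. The series concerns gabapentin, but no sample label names this drug, so no gabapentin comparison was made. Its description says that the drug was given by mouth from day 3, but not to which animals, so it can be part of any difference between model and control. What the control animals were injected with, and when skin was collected, are likewise not given. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these samples. Levels are TMM-normalised CPM (counts scaled to library size), mean ± SD over 6 libraries, and "rose" or "fell" is used of genes with a Benjamini-Hochberg (BH) adjusted p under 0.05 in edgeR's quasi-likelihood (QL) test.

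The comparison of model with control skin asked which genes differed in skin injected with LL37. All 19 interferon-stimulated genes and all 14 monocyte and macrophage markers rose in model skin, as did 13 of 14 endothelial markers, 12 of 13 adipocyte markers, 12 of 24 cytokines and chemokines and 7 of 13 fibroblast matrix genes. Camera with BH adjustment called these lists, but with an estimated correlation it called none of the 27 skin lists (lowest adjusted p = 0.292). Of 19526 genes tested, 3892 passed: 2755 rose and 1137 fell, with 1642 rising and 97 falling at least 2-fold. The number falling rested on single libraries. It was 2554 without skin control 2, 442, 423 and 444 without skin control 3, 5 and 6, and 516, 707, 308 and 496 without skin model 1, 3, 4 and 6. The median log2 change was 1.20 for rising genes and -0.49 for falling genes. In 1697 genes (8.69%, against 0.216% by chance) the 6 model libraries did not overlap the 6 control libraries.

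Chrng, Mymk, Myh3 and Myl4, genes known from forming or regenerating muscle, were among those named for the size or p of their rise. Chrng (gene 11449, chromosome 1, 87205811 to 87211835, GRCm38), the fetal subunit of the muscle acetylcholine receptor, had no counts in the 6 control libraries and 4.05 ± 1.92 CPM in model skin. This was at least 431-fold higher, with a floor of 3 counts over the control group (edgeR QL, BH-adjusted p = 0.000548). Mymk (gene 66139, chromosome 2, 27061636 to 27072161), which encodes the myoblast fusion protein myomaker, rose from 0.037 ± 0.0684 to 5.62 ± 1.73 CPM (edgeR QL, BH-adjusted p = 0.000548). Embryonic myosin heavy chain Myh3 rose 59.6-fold, from 0.851 ± 0.672 to 50.5 ± 22.9 CPM, and Myl4, an embryonic and atrial myosin light chain, rose 11.6-fold, from 1.43 ± 0.434 to 16.6 ± 5.28 CPM. Myl4 had the smallest p in skin (edgeR QL, BH-adjusted p = 0.00017), and for all 4 genes every model library lay above every control library. None of the 13 mature skeletal muscle markers passed in edgeR (1 at an unadjusted p under 0.05, and 0 in DESeq2), with a median log2 fold change of -0.37 (camera, BH-adjusted p = 0.0557, and adjusted p = 0.758 with an estimated correlation). The list passed as lower without skin control 3, 5 or 6 (camera, BH-adjusted p = 0.0346, 0.0258 and 0.013) or skin model 3, 4, 5 or 6 (0.0411, 0.000294, 0.00893 and 0.0386), and with a hair score as a covariate, chosen after the values were seen (0.000295). Myh1 was at 1517 ± 810 CPM in control and 778 ± 424 CPM in model skin, Tcap at 94.3 ± 47.6 and 47 ± 33.8 CPM, and Myh4 at 544 ± 314 and 974 ± 1122 CPM (edgeR QL, BH-adjusted p = 0.124, 0.16 and 0.43).

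**Figure D1:**
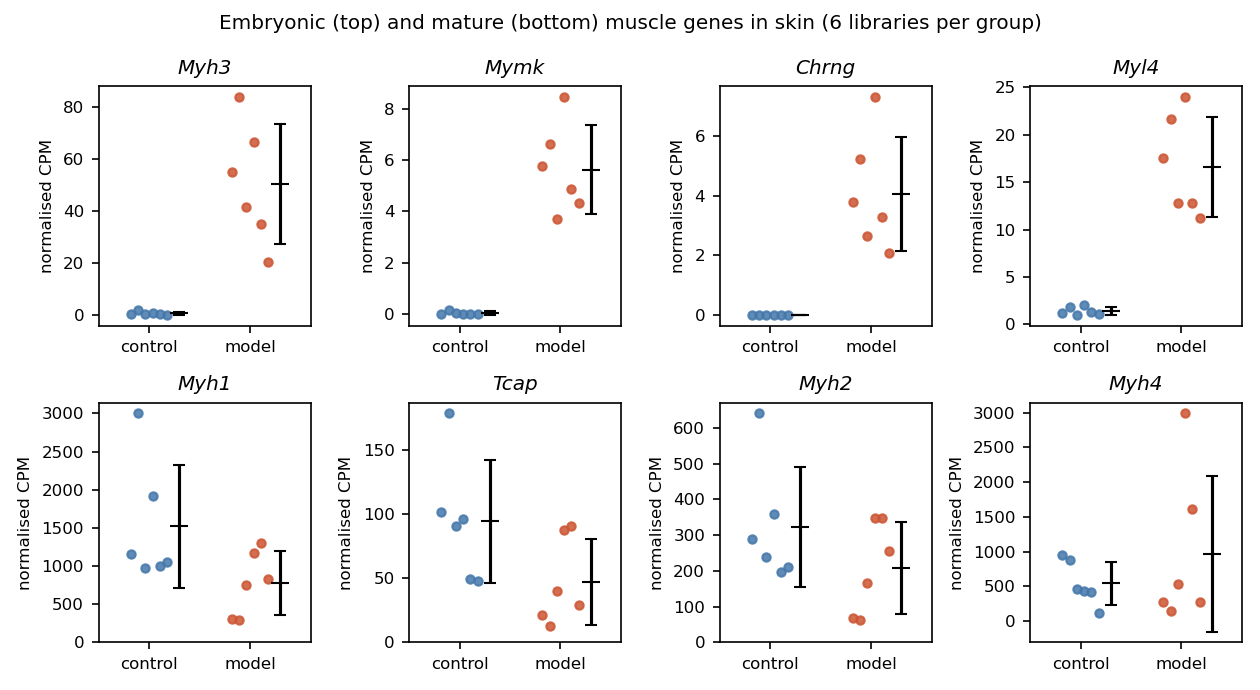
Normalised CPM of embryonic (top) and mature (bottom) muscle genes in 6 control and 6 model skin libraries, with points for libraries and bars for mean ± SD. Myh3 lay between 20.5 and 83.9 CPM in the model libraries and at most at 2.15 CPM in control libraries, while the ranges of Myh1, Tcap, Myh2 and Myh4 overlapped.

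All 19 interferon-stimulated genes rose, with a median log2 fold change of 3.23 (camera, BH-adjusted p = 3.86e-17, and adjusted p = 0.292 with an estimated correlation). Irf7, a transcription factor that amplifies interferon responses, rose 13.6-fold, from 11.7 ± 2.52 to 160 ± 75.4 CPM. Bst2, Zbp1 and Oas1a, products of which restrict or sense viruses, rose 11.1-fold, 13.7-fold and 11.8-fold (edgeR QL, BH-adjusted p = 0.000548 for each). The count was 19 adjusted over the list alone. Among the genes with the largest rises, Slfn4, a myeloid interferon-inducible gene, went from 2.80 ± 1.92 to 362 ± 249 CPM and Ifi206, of the interferon-inducible DNA-sensor family, from 0.0179 ± 0.028 to 2.24 ± 1.25 CPM (edgeR QL, BH-adjusted p = 0.000548 for each). Ifi213, of the same family, was at 0.0116 ± 0.0283 CPM in control and 1.22 ± 0.634 CPM in model skin (edgeR QL, BH-adjusted p = 0.000582). Reads of such closely related genes can be shared between family members.

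Monocyte and macrophage markers rose, and part of the neutrophil markers. All 14 monocyte and macrophage markers rose (14 adjusted over the list alone), with a median log2 fold change of 2.19 (camera, BH-adjusted p = 3.74e-12, and adjusted p = 0.292 with an estimated correlation). Fcgr1, a high-affinity IgG receptor, rose 27-fold to 72.1 ± 36.4 CPM, Ly6c2, a marker of inflammatory monocytes, 8.66-fold to 108 ± 53.5 CPM, and Adgre1, which encodes F4/80, 6.28-fold to 99.2 ± 32.9 CPM. Of 9 neutrophil markers measured, 5 rose (6 adjusted over the list alone), with a median of 1.17 (camera, BH-adjusted p = 0.00585, and adjusted p = 0.346 with an estimated correlation). Retnlg rose from 0.244 ± 0.167 to 16.7 ± 12.7 CPM and Csf3r, the G-CSF receptor, from 3.18 ± 2.2 to 35.8 ± 27.3 CPM (edgeR QL, BH-adjusted p = 0.000553 and 0.00194). With each of the 12 skin libraries left out in turn, Trem1 passed in 7 and Mmp8 in 4 fits. The alarmin genes S100a8 and S100a9 did not pass, at log2 fold changes of -1.01 and -0.23. Cd177, a neutrophil surface protein, Treml2, a receptor of the TREM family, and the acute-phase gene Saa2 were also among the largest rises, reaching 2.95 ± 1.92, 10.8 ± 7.13 and 5.29 ± 5.76 CPM from 0.0296 ± 0.0724, 0.105 ± 0.0796 and 0.0494 ± 0.0835 CPM.

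Dendritic and Langerhans cell markers rose in 11 of 12 cases (11 adjusted over the list alone), with a median log2 fold change of 0.96 (camera, BH-adjusted p = 2.25e-06, and adjusted p = 0.292 with an estimated correlation). The antigen presentation genes Cd74 and H2-Ab1 rose 1.96-fold and 1.81-fold. Mast cell markers rose in 7 of 11 cases (7 adjusted over the list alone), with a median of 1.05 (camera, BH-adjusted p = 0.000329, and adjusted p = 0.346 with an estimated correlation). Tpsab1, which encodes tryptase, rose 5.20-fold, Cma1, chymase, 2.50-fold, and Hdc, the enzyme that makes histamine, 2.72-fold. T cell markers rose in 7 of 12 cases (9 adjusted over the list alone), with a median of 2.54 (camera, BH-adjusted p = 0.000292, and adjusted p = 0.452 with an estimated correlation). Skin model 2 stood apart for these genes, with Cd8a at 21.1 CPM against 0.396 to 2.13 CPM in the other model libraries and 0 to 0.225 CPM in control skin. Cd4 rose from 1.09 ± 0.494 to 9.67 ± 13.3 CPM, with skin model 2 at 36.7 CPM and the other model libraries at 3.56 to 4.86 CPM. Without skin model 2 its log2 fold change was 1.98 (edgeR QL, BH-adjusted p = 0.00113).

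Inflammatory cytokines and chemokines rose in 12 of 24 cases (15 adjusted over the list alone), and the median log2 fold change was 1.62 (camera, BH-adjusted p = 1.18e-08, and adjusted p = 0.292 with an estimated correlation). The monocyte attractants Ccl2, Ccl7, Ccl8 and Ccl12 rose 9.99-fold, 13-fold, 5.08-fold and 15.9-fold (edgeR QL, BH-adjusted p from 0.000548 to 0.0006). Il1b rose 3.21-fold, from 3.36 ± 2.00 to 10.8 ± 7.04 CPM (edgeR QL, BH-adjusted p = 0.0253), with 3 of 6 model libraries above all controls. Of the 16 rosacea-linked innate sensing genes 4 rose (5 adjusted over the list alone, with 1 falling), and the list did not pass, at a median of 0.22 (camera, BH-adjusted p = 0.0582, and adjusted p = 0.591 with an estimated correlation). It passed in fry (BH-adjusted p = 0.0316) and, in camera, without skin control 1 or 4 or skin model 1 (BH-adjusted p = 0.0306, 0.03 and 0.0293). Tlr2, a receptor for bacterial lipoproteins, rose 2.89-fold, from 4.49 ± 2.06 to 13 ± 3.22 CPM, Nlrp3, the inflammasome sensor, 4.47-fold, Tlr4 2.48-fold and P2rx7 1.36-fold (edgeR QL, BH-adjusted p = 0.00419, 0.00123, 0.00145 and 0.00677). Klk5, the protease that cuts cathelicidin into LL37, was at 72.8 ± 18.7 CPM in control and 54.6 ± 20.4 CPM in model skin (edgeR QL, BH-adjusted p = 0.242). Camp, the mouse cathelicidin gene, had 0 to 6 counts per skin library and was not tested. The 9 antimicrobial genes measured did not pass as a list, with a median of -0.23 and a mean of 0.01 (camera, BH-adjusted p = 0.992). Pglyrp1 rose 3.89-fold and Defb1 fell 1.35-fold, the same 1 up and 1 down adjusted over the list alone.

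Endothelial markers rose in 13 of 14 cases (14 adjusted over the list alone), with a median log2 fold change of 0.96 (camera, BH-adjusted p = 1.74e-09, and adjusted p = 0.292 with an estimated correlation). Cdh5, VE-cadherin, rose 2.32-fold, from 24.3 ± 3.96 to 56.3 ± 14.5 CPM, and Pecam1 2.02-fold, from 41.4 ± 8.38 to 83.7 ± 15.7 CPM. Of 16 vascular growth and vasoactive factors 6 rose (7 adjusted over the list alone, with 1 falling), at a median of 0.53 (camera, BH-adjusted p = 0.00314, and adjusted p = 0.292 with an estimated correlation). The nitric oxide synthases Nos3, also an endothelial list member, and Nos2 rose 3.12-fold and 4.67-fold, and Vegfa 1.82-fold, from 39.1 ± 4.89 to 71 ± 28 CPM (edgeR QL, BH-adjusted p = 0.00215, 0.00269 and 0.0138). Fibroblast matrix genes rose in 7 of 13 cases (12 adjusted over the list alone), at a median of 0.83 (camera, BH-adjusted p = 8.22e-06, and adjusted p = 0.346 with an estimated correlation), with Fn1, fibronectin, 2.34-fold higher and Lox, a collagen cross-linking enzyme, 2.25-fold higher. Matrix proteases and their regulators rose in 8 of 13 cases (9 adjusted over the list alone), at a median of 0.96 (camera, BH-adjusted p = 3.67e-05, and adjusted p = 0.346 with an estimated correlation). The protease inhibitor Timp1 rose 7.24-fold and macrophage metalloelastase Mmp12 6.05-fold. Adipocyte markers rose in 12 of 13 cases (12 adjusted over the list alone), at a median of 1.73 (camera, BH-adjusted p = 4.26e-05, and adjusted p = 0.375 with an estimated correlation). Plin1, a lipid droplet protein, rose 3.99-fold to 158 ± 128 CPM and Cfd, adipsin, 3.55-fold to 1140 ± 718 CPM. Msln, which encodes mesothelin, a surface protein of mesothelium, rose 28.2-fold, from 0.27 ± 0.148 to 7.64 ± 2.88 CPM (edgeR QL, BH-adjusted p = 0.000262).

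Some pigment and barrier genes fell in model skin, and hair follicle genes lay lower as a list. The 15 hair follicle keratin and shaft genes had a median log2 fold change of -1.56 (camera, BH-adjusted p = 0.0103, and adjusted p = 0.671 with an estimated correlation), but none passed by itself over all genes or adjusted over the list alone (edgeR QL, 0 of 15, with 4 at an unadjusted p under 0.05 and 4 called in DESeq2). The hair list did not pass in fry (BH-adjusted p = 0.292), and without skin control 2, Krt25, Krt27, Krt71 and Hoxc13 passed as lower (edgeR QL, BH-adjusted p = 0.0172, 0.0158, 0.0187 and 0.0102). All keratin genes, epidermal ones included, with keratin-associated protein genes and Tchh made up 8.22 ± 2.28% of counts in control and 4.34 ± 1.42% in model skin. The ranges were 3.78 to 9.95% and 2.50 to 5.75%, and this share is not of the hair follicle list alone. Of 11 pigment cell genes, a list chosen after the values were seen, 5 passed: Mc1r fell 15.2-fold, Slc45a2 12-fold, Pmel 7.39-fold, Tyrp1 5.96-fold and Dct 5.06-fold (edgeR QL, BH-adjusted p from 0.0319 to 0.0466). With the hair score as a covariate these 5 calls were lost (edgeR QL, BH-adjusted p from 0.107 to 0.177), and the log2 fold change of Mc1r went from -3.93 to -2.72. Their control values were uneven: Pmel was at 44.9, 105 and 184 CPM in skin control 5, 3 and 6, and at 5.18 to 10.2 CPM in the other controls, against 3.70 to 17.8 CPM in model skin. Ptgds, Tmem163 and Gucy2c fell 5.62-fold, 4.11-fold and 3.59-fold. Small and even decreases were seen for Stard10, a phospholipid transfer protein, from 50.7 ± 2.87 to 32.2 ± 4.82 CPM, for Pfn2, an actin-binding profilin, from 61.1 ± 5.89 to 42 ± 5.45 CPM, for the redox protein gene Nxn, and for Zfp692, with every model library below every control library (edgeR QL, BH-adjusted p from 0.000786 to 0.00305).

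Of 19 epidermal barrier genes 3 fell (3 adjusted over the list alone): the junction genes Ocln and Cldn1, 1.42-fold and 1.49-fold, and the desmosomal cadherin Dsc1, 1.83-fold. The list median was -0.27 (camera, BH-adjusted p = 0.0139, and adjusted p = 0.663 with an estimated correlation), and the call was lost in fry (BH-adjusted p = 0.215) and without skin control 2 (adjusted p = 0.116) or skin model 2 (adjusted p = 0.0914). Vasoactive neuropeptides and their receptors rose in 4 of 11 cases (4 adjusted over the list alone), at a median of 0.38 (camera, BH-adjusted p = 0.0284, and adjusted p = 0.346 with an estimated correlation), a call lost without skin control 6 (adjusted p = 0.0986) or skin model 5 (adjusted p = 0.127). The neuropeptide gene Gal rose 37.3-fold, from 0.0415 ± 0.0654 to 1.77 ± 1.35 CPM. Calcrl, the CGRP receptor subunit, rose 1.84-fold, from 13.9 ± 5.45 to 25.5 ± 5.21 CPM (edgeR QL, BH-adjusted p = 0.019), and the PACAP receptor Adcyap1r1 2.32-fold. The CGRP co-receptor Ramp1 was at 11.7 ± 4.24 and 12.4 ± 3.28 CPM (edgeR QL, BH-adjusted p = 0.832).

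The remaining 9 skin lists did not pass in camera. Medians were 1.21 for 6 red blood cell markers, of which 4 rose (4 adjusted over the list alone, with 1 falling), and 0.15 for 11 sebaceous and lipid genes, of which Fasn, Pparg and Dgat2 rose and Mc5r fell (4 up and 2 down adjusted over the list alone). With a library left out in turn, Hba-a2 passed in 6 and Hbb-bt, Hba-a1 and Hbb-bs in 4 of 12 fits. Medians were -0.44 for 13 wound-associated keratinocyte genes, -0.29 for 14 proliferation genes and -0.18 for 8 heat shock genes. None of these passed in edgeR, with 3, 0 and 1 genes at an unadjusted p under 0.05 and 2, 0 and 0 called in DESeq2. The wound list passed as lower without skin control 2 (camera, BH-adjusted p = 0.0204), the proliferation list without skin control 1 or 4 or skin model 2 or 4 (0.0454, 0.0437, 0.0187 and 0.0479), and the heat shock list without skin control 2 or skin model 5 (0.0485 and 0.0397). The median was 0.19, with a mean of -0.02, for 10 sensory receptor channels, of which Trpv2 rose 2.93-fold and Trpv3 fell 1.85-fold. Glucocorticoid-responsive genes had a median of -0.06 and a mean of 0.02 with none passing in edgeR (1 at an unadjusted p under 0.05, and 0 in DESeq2), and circadian clock genes a median of -0.22 with Npas2 rising 1.98-fold, a list that passed as lower with the hair score as a covariate (camera, BH-adjusted p = 0.0291). Immediate early genes had a median of -0.28 and a mean of 0.09, with Fos and Dusp1 rising 2.43-fold and 1.96-fold. For none of these 9 lists, counting also the mature muscle markers, did the adjusted p with an estimated correlation fall below 0.591.

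**Figure D2:**
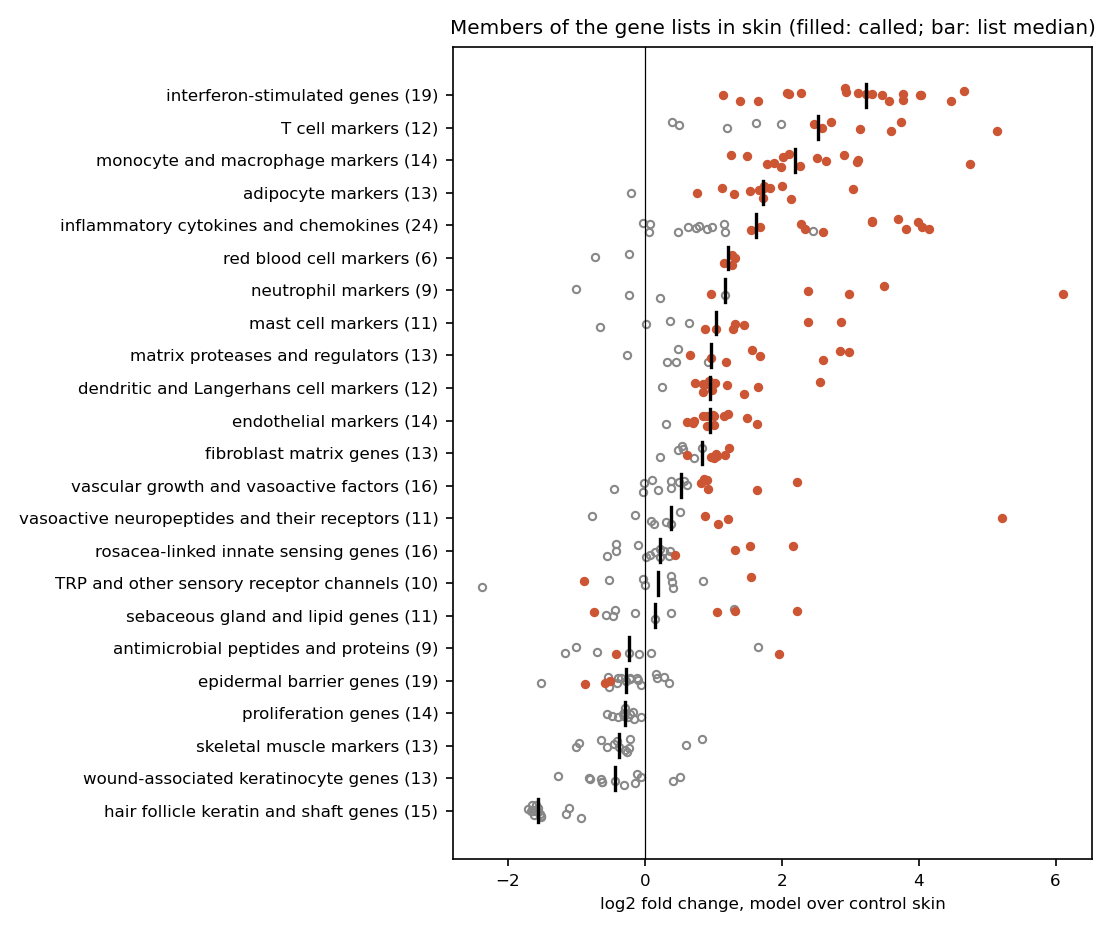
Log2 fold change, model over control skin, of each measured member of 23 gene lists, with filled points for genes that passed and a bar at each list's median. The interferon-stimulated list lay highest, at a median of 3.23, and the hair follicle list lowest, at -1.56.

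The number of genes called in skin depended on single libraries and on the fit: it was 6278 without skin control 2, 2586 without skin control 3, 2564 without skin control 5, 6489 with all 24 libraries in 1 fit and 2232 with 1 surrogate variable as a covariate. Of 98 named skin genes that passed, 78 passed with each of the 12 skin libraries left out in turn. Mc1r, Slc45a2, Pmel, Tyrp1, Dct, Ptgds and Trpv3 passed in 4 of the 12 fits. Tmem163, Gucy2c and Fos passed in 2, Dgat2 in 5, Npas2 in 7, Il1b in 8 and Dusp1 in 10. The share rising was 70.8% with TMM scaling, 65.6% with RLE factors, 62.2% with upper-quartile factors, 56.8% in DESeq2, 51% with all 24 libraries in 1 fit, 85.5% on log2(TPM + 1) and 88.4% without skin model 4. RLE and upper-quartile factors changed the scaling alone. The number of falling genes was 1412 and 1590 with them, against 1137.

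The comparison of model with control DRG asked whether the ganglia differed after LL37 injection into the skin. A small set of genes rose, and several of them are known to be switched on in sensory neurons after nerve injury. Of 19509 genes tested, 19 rose, 13 of them at least 2-fold. In edgeR's QL test 0 genes fell, while 1822 genes in both directions had an unadjusted p under 0.05, and DESeq2 called 118 genes as rising and 18 as falling. The 6 model libraries did not overlap the 6 control libraries in 103 genes (0.528%, against 0.216% by chance).

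Atf3 (gene 11910, chromosome 1, 191170296 to 191183333, GRCm38), a stress-induced transcription factor and a marker of injured neurons, rose 5.48-fold, from 5.71 ± 1.11 to 31.3 ± 4.78 CPM (edgeR QL, BH-adjusted p = 1.62e-06). Sprr1a (gene 20753, chromosome 3, 92483954 to 92485881), a cornified envelope gene also induced in regenerating axons, rose 76.2-fold, from 0.241 ± 0.186 to 18.6 ± 7.46 CPM (edgeR QL, BH-adjusted p = 0.00032). Gal (gene 14419, chromosome 19, 3409915 to 3414544), which encodes the neuropeptide galanin, rose 3.63-fold, from 18 ± 3.86 to 65.3 ± 18.8 CPM (edgeR QL, BH-adjusted p = 0.00335). The orphan receptor gene Gpr151 rose 4.07-fold, from 1.52 ± 0.212 to 6.21 ± 1.83 CPM, and the stress response gene Gadd45a 1.63-fold, from 12.2 ± 0.781 to 19.8 ± 1.94 CPM (edgeR QL, BH-adjusted p = 0.00032 and 0.000547). Each of these genes was higher in all 6 model libraries than in any control library. Of 15 nerve injury genes measured 6 rose (8 adjusted over the list alone): Atf3, Sprr1a, Gal, Gadd45a, the adhesion protein gene Flrt3 and the transcription factor gene Sox11. The list median was 0.70 (camera, BH-adjusted p = 6.52e-21, and adjusted p = 0.0111 with an estimated correlation).

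**Figure D3:**
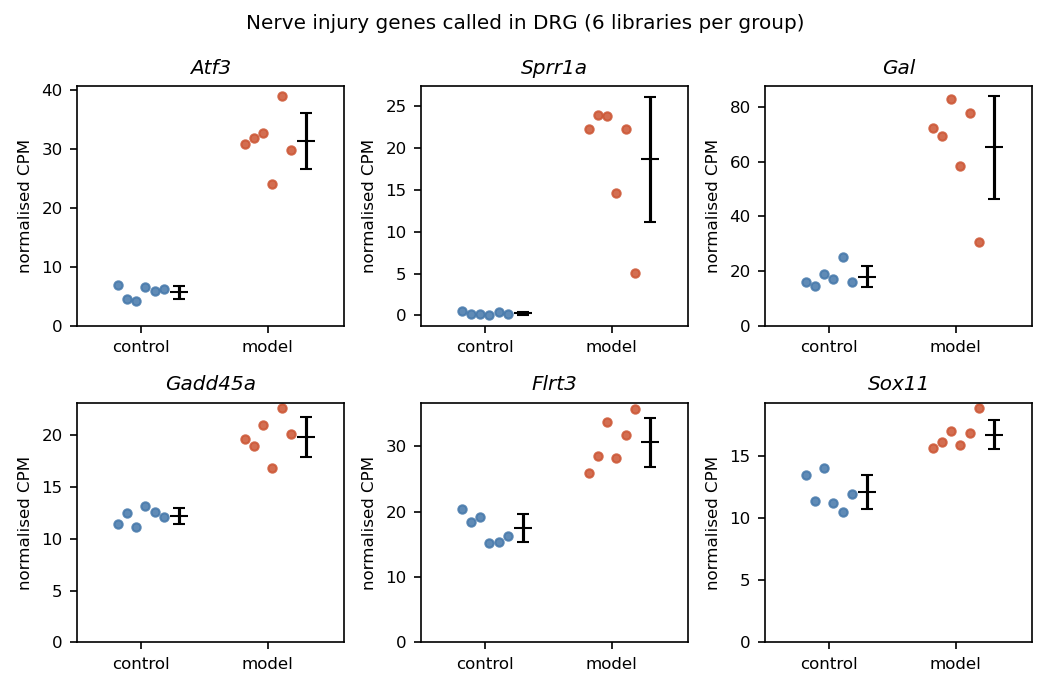
Normalised CPM of the 6 nerve injury genes called in DRG, with points for the 6 control and 6 model libraries and bars for mean ± SD. Atf3 lay between 24.1 and 38.9 CPM in model DRG and between 4.19 and 6.88 CPM in control DRG.

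Flrt3 rose from 17.5 ± 2.15 to 30.6 ± 3.69 CPM and Sox11 from 12.1 ± 1.38 to 16.7 ± 1.18 CPM (edgeR QL, BH-adjusted p = 0.00176 and 0.0407). Fst, which encodes the activin antagonist follistatin, rose 1.81-fold, and the motor protein gene Myo10 1.32-fold, while the guidance molecule gene Sema6a rose from 14.2 ± 1.16 to 21.3 ± 2.62 CPM (edgeR QL, BH-adjusted p = 0.0036, 0.00553 and 0.0121). Star, a steroid synthesis gene, rose 2.09-fold, the serotonin transporter gene Slc6a4 8.34-fold and the keratinocyte gene Krtdap 10.2-fold, from 0.109 ± 0.0658 to 1.16 ± 0.718 CPM (edgeR QL, BH-adjusted p = 0.0215, 0.0281 and 0.0292). The Langerhans cell gene Cd207 rose from 0.0853 ± 0.0447 to 0.557 ± 0.151 CPM (edgeR QL, BH-adjusted p = 0.0152). Another 4, outside the naming rule for this comparison because they stayed under 1 CPM and given here after their values were seen, were Kcnk16, Lipn, Gm5152 and Tnfrsf8, at 0.94, 0.767, 0.636 and 0.41 CPM in model DRG. With each of the 12 DRG libraries left out in turn, the 11 genes Atf3, Sprr1a, Gpr151, Gadd45a, Kcnk16, Lipn, Flrt3, Gm5152, Gal, Fst and Myo10 passed in 12 of 12 fits. Sema6a passed in 10, Cd207 in 7, Star, Slc6a4 and Krtdap in 4, Sox11 in 2 and Tnfrsf8 in 1.

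Apart from Gal, no gene in the lists that define sensory neuron types passed. Calca, which encodes CGRP, was at 1192 ± 131 CPM in control and 1069.9 ± 103 CPM in model DRG, and Tac1, which encodes substance P, at 183 ± 30.3 and 167 ± 27.6 CPM (edgeR QL, BH-adjusted p = 0.573 and 0.762). The heat and irritant channel genes Trpv1 and Trpa1 were at 139 ± 14.5 and 112 ± 16.8 CPM in control and 136 ± 21.3 and 108 ± 17.7 CPM in model DRG, and Adcyap1, which encodes PACAP, at 92.6 ± 14.7 and 98.3 ± 11.9 CPM (edgeR QL, BH-adjusted p = 0.957, 0.906 and 0.832). The calcium channel subunit genes Cacna2d1 and Cacna2d2, whose products bind gabapentin, were at 289 ± 49.9 and 132 ± 20.1 CPM in control and 303 ± 24.7 and 127 ± 10.3 CPM in model DRG (edgeR QL, BH-adjusted p = 0.877 and 0.883). In simulated DRG counts with the same spread, edgeR recovered 86.6% of genes changed 2-fold and 64.2% of those changed 1.5-fold. The simulation gave 173 calls against 19 in the real data, so its limit on unadjusted p was looser and these rates are too high here. The 4 lowest p-values among decreases, none of which passed, belonged to Arxes2, the neuregulin receptor gene Erbb4, the itch receptor family gene Mrgpra2a and Klhl1 (edgeR QL, BH-adjusted p = 0.254 for each). Their log2 fold changes were -0.25, -0.72, -0.26 and -0.86.

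Neuron type and channel lists did not pass in camera, except that the non-peptidergic and itch neuron list passed as lower without DRG control 4 (median -0.08, BH-adjusted p = 0.0281). Peptidergic nociceptor genes had a median log2 fold change of -0.05 and a mean of 0.14 with Gal as the only 1 of 10 that rose (1 adjusted over the list alone), and vasoactive neuropeptides and their receptors a median of 0.04, again with Gal alone. Medians were -0.04 for 13 non-peptidergic and itch neuron genes, 0.02 for 10 large-fibre genes, -0.03 with a mean of 0.04 for 15 calcium channel subunits, 0.03 for 13 sodium, potassium and pacemaker channels, and -0.03 with a mean near 0 for 12 sensory receptor channels. No member of these 5 lists passed over all genes or adjusted over the list alone. The DRG lists of satellite glia (-0.05), monocyte and macrophage (-0.01, with a mean of 0.05), mast cell (0.09), endothelial (0.03), red blood cell (0.83), cytokine (0.29), innate sensing (0.09), vascular factor (0.02), glucocorticoid (-0.01), immediate early (-0.01) and heat shock genes (-0.09) had no member that passed and did not pass in camera. Without DRG control 6 the endothelial, red blood cell, vascular factor and dendritic lists passed as higher (camera, BH-adjusted p = 7.53e-06, 0.0294, 0.00521 and 0.0486), the endothelial median being 0.30, and without DRG model 6 the first 3 did (0.0482, 0.0245 and 0.0135). Without DRG control 5 and DRG model 5 the mast cell list passed (0.0465). Cd207 was the only 1 of 10 dendritic and Langerhans cell markers to rise (median 0.05). No circadian clock gene passed over all genes, with 1 rising adjusted over the list alone and a median of -0.03 against a mean of 0.03. T cell markers (2 measured) and central oligodendrocyte and spinal cord markers (3 measured, with 3 falling adjusted over the list alone) were too few for the list test. The latter 3, Gad1, Mobp and Aqp4, were at 41.6, 208 and 61.6 CPM in DRG control 5, against at most 1.18, 32.8 and 10 CPM in the other DRG controls. In the 25 DRG lists without a called gene, 32 of 288 members had an unadjusted p under 0.05 in edgeR and DESeq2 called 2.

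Another 6 DRG lists passed in camera without a single member passing, and none of these calls held with an estimated correlation. Medians were 0.22 for interferon-stimulated genes (camera, BH-adjusted p = 0.00294), 1.19 for neutrophil markers (0.00621), 0.17 for skeletal muscle markers (0.0151), 0.53 for proliferation genes (0.0194) and -0.19 for Schwann cell myelin genes (0.0194), each with adjusted p = 0.787 with an estimated correlation. The median was 0.56 for adipocyte markers (camera, BH-adjusted p = 0.00307, and adjusted p = 0.599 with an estimated correlation), of which 1 rose adjusted over the list alone. Some libraries held transcripts of other tissue: DRG control 5 had Gad1 at 41.6 and Gfap at 267 CPM, against at most 1.18 and 41.7 CPM in the other DRG libraries, and DRG model 5 had the marrow precursor gene Mpo at 50.4 and Ngp at 165 CPM, against at most 24.1 and 37.2 CPM. Without DRG model 5 the neutrophil median was 0.155 and the proliferation median -0.001 (camera, BH-adjusted p = 0.227 and 0.834). The neutrophil, interferon and proliferation calls were also lost without DRG control 5, at adjusted p of 0.0774, 0.0833 and 0.148, and the interferon call without DRG model 3, at 0.0951. Proliferation was further lost without DRG control 2 and 3 (0.0566 and 0.0507), muscle without DRG control 1 and 3 and DRG model 1 and 6 (0.0622, 0.22, 0.0738 and 0.166, with the median turning to -0.02, -0.08, -0.05 and -0.08), and Schwann myelin without DRG control 1 and 2 and DRG model 1, 5 and 6 (0.224, 0.124, 0.102, 0.116 and 0.113).

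The DRG call count was 36 without DRG model 6, 11 without DRG control 1, 11 without DRG control 4, 12 without DRG model 3, 12 with a stricter filter, 33 with all 24 libraries in 1 fit and 136 in DESeq2. Without DRG control 5 and DRG model 5, a pair chosen after the values were seen, 20 genes rose, 15 of them among the 19.

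The direct comparison of both tissues asked which genes responded differently to the model in skin and DRG. The effects on Myl4, Mymk and Myh3 were higher in skin than in DRG, and that on Sprr1a was higher in DRG, with the difference itself tested. The test of the difference passed for 2942 of 17251 genes, with a higher skin effect in 1832 and a lower one in 1110. Myl4, Mymk and Myh3 had skin effects higher by 3.46, 7.38 and 6.13 on the log2 scale, and Aldh3b1, an aldehyde dehydrogenase gene, by 2.25 (edgeR QL, BH-adjusted p = 4.3e-07, 5.62e-07, 5.62e-07 and 3.24e-06). In the other direction, the difference was -6.94 for Sprr1a, which in skin was at 1827 ± 610 CPM in control and 1173 ± 281 CPM in model libraries and passed as lower without skin control 2 (log2 fold change -0.82, edgeR QL, BH-adjusted p = 0.00406), and -6.20 for the epidermal lipase gene Lipn, which in DRG was at 0.00969 ± 0.0237 and 0.767 ± 0.277 CPM (edgeR QL, BH-adjusted p = 4.3e-07 and 9.5e-05). Sema6a and Flrt3 moved in opposite directions, falling in skin (log2 fold change -0.50 and -0.86) and rising in DRG (0.59 and 0.81), with differences of -1.14 and -1.72 (edgeR QL, BH-adjusted p = 0.000165 and 0.000239). The falls in skin passed at BH-adjusted p of 0.0249 and 0.0266 (edgeR QL), and whether they hold with single skin libraries left out is not given here.

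**Figure D4:**
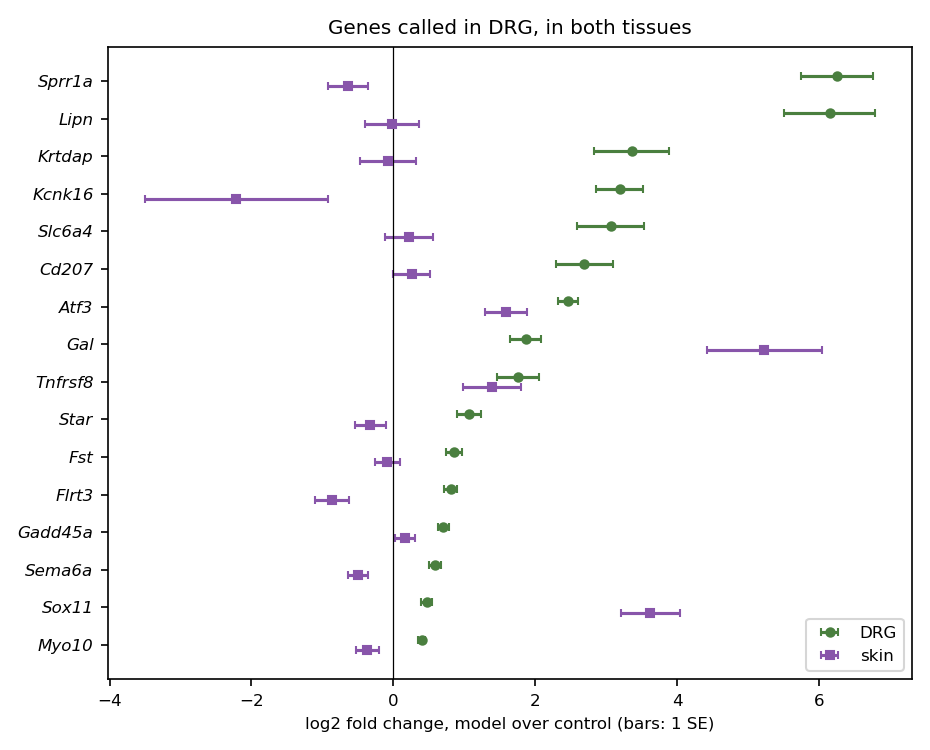
Log2 fold change, model over control, with 1 SE, in DRG (circles) and in skin (squares) of 16 of the 19 called DRG genes, all tested in both tissues. Sprr1a was at 6.25 in DRG and -0.64 in skin, and Gal at 1.86 in DRG and 5.22 in skin.

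Among genes tested in both tissues, 2450 rose in skin and 17 in DRG. Both sets shared 4 genes, against 2.41 expected by chance (Fisher's exact test, two-sided p = 0.288): Atf3, Gal, Sox11 and Tnfrsf8. In skin Atf3 rose from 7.47 to 22.5 CPM, and the skin effects of Gal and Sox11 exceeded those in DRG by 3.29 and 3.10 on the log2 scale (edgeR QL, BH-adjusted p = 0.00471 and 1.68e-05). The log2 fold changes of both tissues were correlated at Pearson's r = 0.16 and Spearman's rho = 0.0561 across 17251 genes, which are not independent replicates. With scaling factors taken within each tissue, 2828 genes passed the test of the difference, 2174 with a higher and 654 with a lower skin effect (76.9% higher, against 62.3%), so the split by direction depends on the scaling. The overlap was 2 genes with the stricter filter, 23 in DESeq2 and, at an unadjusted p under 0.01 in both tissues, 67 rising and 9 falling (Fisher's exact test, two-sided p = 0.00011 and 0.0999).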

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

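The tests of skin RNA in the DRG, of more skeletal muscle, of a lower epithelial share and of single gene lists over the splits were chosen after the result was seen.

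A library was set apart where its gap to the nearest of the other 5 was a larger share of the range of its group than Dixon's 95% critical value for 6 (log2 CPM for genes, percent of counts for shares). This held in 51 of 540 groups of values (9.44%), where chance gives about 5%, and the ratios are given after each gene. Skin control 2 was set apart for 11 genes. It was low for Krt25 (0.893), Krt27 (0.884), Krt71 (0.878) and Hoxc13 (0.716) of the hair follicle, and for S100a7a (0.926), Sprr1a (0.896), Tgm1 (0.888), Areg (0.778), Krt17 (0.774), Gucy2c (0.668) and Trpm8 (0.667). Its share of counts from all keratin genes, keratin-associated protein genes and Tchh was low (0.726), and its mitochondrial share was high (0.874). Skin model 1 was high in mitochondrial share (0.776) and in the share of the 10 most abundant genes (0.678). Skin model 5 was low for the macrophage genes Cd68 (0.791), Adgre1 (0.691) and Fcgr1 (0.664), for Fn1 (0.679) and Pglyrp1 (0.648), and for the interferon-stimulated genes Irf7 (0.664) and Oas1a (0.634). Skin model 2 was high for Cd4 (0.867), Cd2 (0.73) and Flt3 (0.636). Among the other skin controls, control 3 was high for Ifi213 (1) and Stard10 (0.728), control 4 high for Cd177 (1), and control 5 low for Cd8a (0.627) and high for Fos (0.665). Ifi213 and Cd177 were at only 0.0693 and 0.177 CPM in these libraries and at 0 CPM in the other controls, which by itself gives a ratio of 1.

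DRG control 5 was set apart for 8 genes, among them 7 given here: high for Adcyap1r1 (0.936), Gad1 (0.909), Aqp4 (0.895), Hcn2 (0.852), Sst (0.816) and Klhl1 (0.635), and low for Nod2 (0.632). DRG model 5 was high for Dnajb1 (0.903) and Hdc (0.755), and DRG model 6 low for the nerve injury genes Sprr1a (0.682) and Gal (0.648). Single genes set other DRG libraries apart. These were Myh2 in control 1 (0.696, low), Car3 and Arntl in control 2 (0.739 and 0.676, high), and Trpa1 and Cacna2d4 in control 3 (0.777, high, and 0.636, low). Others were Itgax in control 4 (0.743, low), Cd207 in control 6 (0.787, low), Sst in model 1 (0.688, high) and Cysltr2 in model 2 (0.6252, low).

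The model effect differed between skin and DRG, by a test of the difference itself, in 2942 genes. Skin minus DRG on the log2 scale, the skin effect was higher for Mymk (7.38), Myh3 (6.13), Retnlg (4.92), Myl4 (3.46), Gal (3.29), Cd4 (3.10), Sox11 (3.10), Adcyap1r1 (2.52), Cd68 (2.27), Aldh3b1 (2.25), Fos (2.12), Trpv2 (1.56), Cma1 (1.07) and Cdh5 (0.77). It was lower for Sprr1a (-6.94), Lipn (-6.20), Krtdap (-3.45), Slc6a4 (-2.86), Cd207 (-2.48), Flrt3 (-1.72), Star (-1.43), Sema6a (-1.14), Fst (-0.98), Myo10 (-0.81) and Gadd45a (-0.58), and for Kcnk16 (-5.46), which was chosen after its values were seen. The difference for Adcyap1r1 rests in part on DRG control 5, at 39.8 CPM against 4.32 to 4.98 CPM in the other DRG controls. That for Cd4 rests in part on skin model 2, at 36.7 CPM against 3.56 to 4.86 CPM in the other model skin libraries.

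In 100 splits of the 12 skin libraries into groups of 6, the real split included, 1 called as many as 3892 genes, and the highest other called 1757. In DRG 1 of 100 called as many as 19 genes, with 7 in the highest other. For the tissue difference 1 of 100 called as many as 2942, with 1114 in the highest other. Chance alone is thus unlikely for these 3 counts, though 1 of 100 is the lowest result that 100 splits can give. The splits also take libraries as separate samples, which the labels do not state. The splits decide nothing on the overlap: 1 of 100 shared as many as 4 genes and the highest other shared 0, but 0 of the other splits called genes in both tissues. Given the numbers called, 2.41 shared genes were expected (Fisher's exact test, p = 0.288), while at an unadjusted p under 0.01 the 67 shared rising genes had p = 0.00011 in the same test, which takes genes as independent. Chance cannot be excluded for the number of lists called by camera: 28 of 100 skin splits called as many as 15 lists (highest other 19), and 51 of 100 DRG splits as many as 7 (highest other 16). Splits whose groups hold unequal numbers of controls keep part of the difference between model and control, which can raise such counts. The split with 1757 skin genes had 5 controls in 1 group. Skin splits with 3 controls in each group also called 15 and 16 lists. Of single lists, the median of interferon-stimulated genes in skin (3.23, highest other 2.99) and of nerve injury genes in DRG (0.704, highest other 0.494) was reached in 1 of 100 splits. Of the other lists called in skin, the median was reached in 42 splits for epidermal barrier genes, 9 for neutrophil markers, 8 for vasoactive neuropeptides, 4 for matrix proteases, 3 for hair follicle genes and 1 for each of the rest. In DRG it was reached in 83 for muscle, 44 for proliferation, 25 for neutrophil, 18 for Schwann myelin, 14 for interferon-stimulated and 3 for adipocyte genes. Camera gave a p as small in 1 split for interferon-stimulated and endothelial genes in skin and nerve injury genes in DRG, in 2 for macrophage and dendritic markers in skin, and in 6 to 46 for the other skin and 9 to 53 for the other DRG lists called.

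Nerve injury genes such as Atf3, Sprr1a and Gal rose in model DRG. Skin RNA in these libraries was argued against: Krt5 and Krt14 summed to 0.182 CPM in model DRG (0.324 in the highest library), where the level of Krtdap would need 17.5 and that of Sprr1a 129 CPM. Spinal cord or marrow tissue in DRG control 5 and DRG model 5 was argued against as well, since 15 of the 19 genes were called without them. This was the least number set beforehand for this reading, and the median log2 change of the 19 genes went from 1.86 to 1.93. Of the nerve injury genes, Sox11 was no longer called (edgeR QL, BH-adjusted p = 0.106). DRG control 6, with Gfap at 41.7 and Mpo at 24.1 CPM, stayed in. So did DRG model 2, 3 and 4, with Mpo at 6.44, 8.4 and 6.97 CPM, against 1.09 to 4.32 CPM in DRG control 1 to 5. Smaller amounts of such tissue in other libraries, more of them model libraries for Mpo, were thus not tested. LL37, the injection itself and gabapentin stay open and were untested, here and for the next patterns, as what the controls were injected with and which animals received the drug are not given in the sources used here.

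Mymk, Myh3, Myl4 and Chrng, genes of embryonic muscle, rose in model skin. A larger amount of muscle in the samples was argued against, with a median log2 change of -0.374 for 13 mature muscle markers (bootstrap interval over libraries, from log2 CPM, -1.73 to 0.355). Another 10 genes were listed as muscle precursor genes before their values were seen, and all were also measured in control skin. Of these 7 rose (Actc1, Cdh15, Myf5, Msc, Tnnt2, Cdkn1c and Megf10), with a median of 1.35, and Myf6, Fgfr4 and Lrrn1 did not pass. The lowest p belonged to Tnnt2, Actc1 and Cdkn1c (edgeR QL, BH-adjusted p = 0.000548, 0.000553 and 0.00101). Myf5 and Msc were at only 0.902 and 0.966 CPM in model skin. Activated muscle precursors may account for the pattern, and so may forming or regenerating muscle fibres. Whether these genes tell precursors from such fibres was not tested. Damage by the needle or the injected volume, as against LL37, stays open and was untested.

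Of 27 endothelial and fibroblast genes 20 rose in model skin. With the hair score as a covariate their median was 0.785 instead of 0.915 (ratio 0.858, bootstrap interval, from log2 CPM, 0.341 to 1.09), and 18 instead of 20 were called. A lower hair content and a change in these cells cannot be told apart, because this interval spans 0.5. A lower epithelial share alone would raise endothelial, fibroblast, adipocyte, mature muscle and macrophage genes all alike, and these 5 lists did not move alike. Their medians spanned 2.56, from -0.374 (-1.73 to 0.355) for mature muscle to 2.19 (1.61 to 2.78) for macrophages. These medians were known when the test was chosen, so its outcome was fixed and it cannot count against a lower epithelial share. It does not decide on the endothelial, fibroblast and adipocyte lists, whose intervals overlap, at medians of 0.957 (0.669 to 1.21), 0.828 (0.443 to 1.3) and 1.73 (0.764 to 2.12). For these a lower epithelial share stays open. Growth of vessels and matrix in inflamed skin stays open and was untested.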

How the results depend on the processing

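All settings here were chosen before the data were examined, except the hair score covariate, the omission of DRG control 5 with DRG model 5, and the omission of single libraries for the list tests. In skin, where 3892 genes were called, the count was 6489 with all 24 libraries in 1 fit and 2232 with 1 surrogate variable. It was 1739 at an absolute log2 fold change of at least 1, where fewer genes can pass, and ranged from 2564 (without skin control 5) to 6278 (without skin control 2). The other settings chosen beforehand, without a block, gave 3178 to 5551 genes, and the median log2 change of all genes stayed between -0.06 and 0.01. With the hair score as a covariate 2956 genes were called, 2753 of them in common. In DRG, where 19 were called, the count was 136 in DESeq2, 12 with at least 1 CPM in 6 libraries, where fewer genes are tested, and 33 with all 24 libraries in 1 fit. It ranged from 11 (without DRG control 1 or 4) to 36 (without DRG model 6). In skin, where 15 lists were called, camera with an estimated correlation called 0 and fry 14 (13 shared), and 15 to 17 were called with single libraries left out. In DRG, where 7 were called, an estimated correlation gave 1 and fry 1, with 4 (without DRG control 5 or DRG model 5) to 11 (without DRG control 6, 7 shared) with single libraries left out. The count for the tissue difference, 2942, was 2582 to 3834 in the settings without a block. The 4 genes shared by skin and DRG became 76 at an unadjusted p under 0.01 (47.5 expected, Fisher's exact test, p = 0.00011 for the 67 rising), 2 with the stricter filter, where fewer genes are tested, and 23 in DESeq2 (19.7 expected). Apart from the thresholds and filters, where the construction gives it, the cause was not tested.

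With the hair score as a covariate the hair follicle list median turned from -1.56 to 0.0017 (adjusted p = 0.969), as the covariate is built from these genes. The DRG proliferation median turned from 0.53 to -0.087 (adjusted p = 0.726) without DRG control 5 and DRG model 5. With RLE factors 131 named skin genes and 128 named DRG genes kept their direction and side of the threshold, and 3 more skin genes passed. In DESeq2 these were 120 and 118, and 12 more skin and 6 more DRG genes passed. The numbers in the titles are not stated to pair samples. With the replicate number as a block, skin gave 2804 genes, DRG 6 (Atf3, Sprr1a, Gpr151, Kcnk16, Lipn and Gal) and the tissue difference 2069. With it 12 named skin and 11 named DRG genes no longer passed, and 1 skin gene and the innate sensing list in skin (adjusted p = 0.0453) did. Correlations of samples sharing a number ranged from -0.51 to 0.26 between control and model skin, from -0.38 to -0.051 in DRG, from -0.042 to 0.079 between skin and DRG in controls (2 of 6 matched their own number best) and from -0.14 to 0.062 in the model (1 of 6).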

Other observations

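The pigment cell list, the comparison of spinal cord and marrow genes, and the tests with the hair score were chosen after the result was seen.

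Of 11 pigment cell genes 5 fell in model skin, with a median log2 change of -2.88. With the hair score as a covariate 0 fell in edgeR, with 4 decreases at an unadjusted p under 0.05 and a median of -1.90; no other tool was run with this covariate. With the same covariate all 19 interferon-stimulated genes passed, with a median of 2.97, and so did 13 macrophage markers.

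DRG control 5 held Gad1 at 41.6, Gfap at 267, Mobp at 208 and Slc6a11 at 63.5 CPM, against at most 1.18, 41.7, 32.8 and 3.99 CPM in the other DRG libraries. DRG model 5 held the marrow genes Mpo, Ngp and Elane at 50.4, 165 and 13.9 CPM, and DRG control 6, the next highest, at 24.1, 37.2 and 8.83 CPM. Mpo was at 6.44, 8.4 and 6.97 CPM in DRG model 2, 3 and 4, at 1.67 and 1.71 CPM in DRG model 1 and 6, and at 1.09 to 4.32 CPM in DRG control 1 to 5. Mitochondrial transcripts were 3.84 ± 1.03% of counts in control skin and 5.03 ± 1.66% in model skin.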
